A study of Caenorhabditis elegans with 12 samples.

How the data were processed

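RNA splicing was measured in 12 RNA-seq libraries of whole Caenorhabditis elegans at the L3 larval stage. Per the labels' protocols, embryos were isolated by bleaching, grown for 34 hours at 20 °C on bacterial lawns, lysed in Trizol, depleted of ribosomal RNA and sequenced as paired reads of 150 nt. The libraries formed 4 groups of 3, which were N2 numbered az021 to az023 (N2 az02), sacy-1(tn1385) numbered az024 to az026, N2 numbered az041 to az043 (N2 az04) and mog-5(az192) numbered az044 to az046. Which N2 set belonged with which mutant was taken from the library numbers in the titles, since the labels do not state it. The labels did not say whether the libraries of a group came from separate cultures, so p-values measured only the spread between these libraries, which may be technical.

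The authors' 24 files were lists of splicing events, 2 per library, on genome build ce10 per the file headers. The submitters' processing notes name Bowtie2, STAR and SAMtools, without versions, roles or order, and the annotation behind each catalogue beyond its name was not given in the sources used here. The deposited value of each event was a per mille score for its included and its excluded form. One catalogue, named for library introns in the file headers, held alternative 3′ and alternative 5′ splice sites, and in it the 2 scores always summed to 1000. The other, named for Ensembl archive 65, held alternative first exons, alternative last exons, mutually exclusive exons, skipped exons, multiple skipped exons and retained introns. Its 2 scores often summed to less than 1000, and what that sum stands for was not stated in the sources used here.

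Percent spliced in was computed as the included score over the sum of both scores, in percent. No read totals were used here, so the depth behind each value was unknown, and no interval or detection limit that needs it was given. Many values stood at exactly 0.1% or 99.9%, although others lay outside that range, and why was not given in the sources used here. In the library-intron catalogue 799 to 1123 events per library stood at 0.1% in N2 az02 and 537 to 757 in N2 az04. In sacy-1 it was 332 to 439 and in mog-5 322 to 412. At 99.9% the counts were 303 to 510, 216 to 412, 424 to 473 and 319 to 363 in the same order. Whether depth had a part in this could not be checked. All 5267 events of the library-intron catalogue were checked for geometry, and in each the included form had the shorter intron and shared the other intron end. For an alternative 3′ splice site the included form therefore used the upstream acceptor, the one nearer to the 5′ splice site, and the stretch between both acceptors was exonic in that form and intronic in the other. Acceptor positions are given as the exonic base that follows the intron, 1-based. No pair of libraries within a group was identical, since 22.9% to 31.6% of events differed by at least 5 percentage points between any 2 of them.

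An event was tested when it was listed in all 6 libraries of a comparison. Group differences in percent spliced in were tested with limma 3.58.1 in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment within each catalogue. This test draws the spread of each event towards that of all events. Where an event had an SD of 0 in both groups, its p-value therefore rested on the spread of the other events. An event was called changed at an adjusted p below 0.05 and a difference of at least 15 percentage points. The plan had foreseen a test on read counts of each form with a minimum of 10 reads, and limma on percent spliced in if only percentages were given, which was the case, so the read minimum was not applied. The 3 comparisons were sacy-1 against N2 az02, mog-5 against N2 az04 and N2 az04 against N2 az02. The difference between both mutant effects was tested as an interaction term in 1 fit of all 12 libraries. Event types and overlaps were compared with Fisher's exact test and the direction of changes with an exact two-sided binomial test, both over events, and group means over distance bins with exact permutation tests. Events are not independent, since they share the same libraries and in places a gene. Bins of 1 to 6, 7 to 18 and 19 to 60 nt between both sites were fixed before the data were examined, and the longest distance listed for tested alternative 3′ splice sites was 50 nt.

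The events named in the text followed a rule fixed before the data were examined. Among changed events in which the 3 mutant libraries lay on 1 side of the 3 N2 libraries, it took the 10 alternative 3′ events with the largest difference per mutant, the 3 with the largest difference of each other type, and the 5 changed in both mutants with the largest smaller difference. It also took the 3 tested library-intron events with the smallest adjusted p of the interaction, changed or not. Overlapping events on a strand counted as 1 locus in place of 1 gene, with 1 event taken per locus, and the rule was extended to the Ensembl catalogue after it was seen which types each catalogue held. A few further events, named as such, were chosen after their values were seen. The files do not pair events with gene names, and the gene tables at hand were on another build, so no genes were named. The prepared lists of splicing, germline, muscle, neuron, ribosomal, cuticle and heat shock genes were therefore not used here.

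The test was run first on simulated percentages with the means and spreads of each comparison and 200 events moved by 20 or 40 points. The noise was normal, with 1 pooled SD for both groups of an event. Groups of unequal spread, such as 1 with an SD of 0 against 1 without, were not covered, so the false calls hold for this setting only. In the library-intron catalogue it recovered 58.4% of the 20-point and 77.5% of the 40-point changes for sacy-1, over 5069 simulated events with 3 false calls. For mog-5 it recovered 77% and 82%, over 5172 simulated events with 1 false call. In the Ensembl catalogue it recovered 80.2% and 93.3% for sacy-1 over 2382 events and 81.6% and 93.1% for mog-5 over 2498 events, with 0 false calls in either. Alternatives covered an arcsine square root scale, a rule on all pairs of libraries without p-values, other minimum differences, the other N2 set, all 6 N2 libraries, 1 fit of all 12 libraries and leaving out each library. Tables were made with Python 3.11.15 and pandas 2.3.3 and plots with matplotlib 3.10.9.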

Results

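The study compared splicing in larvae of wild-type N2 with larvae carrying a variant of a spliceosomal helicase. SACY-1 is the worm counterpart of human DDX41, a DEAD-box helicase found in spliceosomes, and MOG-5 is the counterpart of PRP22, a helicase that acts late in splicing and releases the spliced mRNA. The question, as the series title gives it, was whether both proteins act against the use of the 3′ splice site nearer to the start of the intron. Percent spliced in was available for 5201 to 5254 alternative 3′ and 5′ splice site events per library in the library-intron catalogue, and for 2459 to 2567 events of the other types in the Ensembl catalogue. Read depth was unknown. The mean SD between the 3 libraries of a group, over the 5019 library-intron events listed in all 12 libraries, was 5.17 percentage points in N2 az02, 5.03 in sacy-1, 3.41 in N2 az04 and 3.87 in mog-5.

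In sacy-1(tn1385) larvae, splicing moved to the upstream acceptor of closely spaced acceptor pairs. Of 3370 alternative 3′ splice site events tested, 313 changed, and 310 of these used the upstream acceptor more than N2 az02 did. All 309 changed events with acceptors up to 18 nt apart moved upstream, 85 of them at 1 to 6 nt and 224 at 7 to 18 nt. The median upstream use over the 313 changed events was 13.1% in N2 az02 and 50.1% in sacy-1. Over all 1725 events of 7 to 18 nt listed in every library, mean upstream use was 30.1% ± 0.33 (SD, n = 3) in sacy-1 and 22.1% ± 0.62 in N2 az02.

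The changes called by limma lay on 1 side of an even split by an exact two-sided binomial test over events (p = 6.13e-88). However, an event with less upstream use in N2 az02 than the minimum difference could only be called upstream. The median N2 az02 use over the called events, 13.1%, lay below that minimum. An even split was therefore not a fair base, and the p-value overstates how far the direction was free to vary. All events share the same 6 libraries, so a shift of a whole library set could also give such a p-value. None of the events up to 18 nt was called in the downstream direction by limma or on the arcsine square root scale, and 27 of them leaned downstream at an unadjusted p below 0.05. The difference in mean upstream use was 7.99 points at 7 to 18 nt and 5.25 points at 1 to 6 nt, where the means were 45.2% ± 0.43 and 39.99% ± 0.83. Both gave p = 0.1 in an exact two-sided permutation test, the smallest p that 3 libraries against 3 allow, and 0.3 after adjustment over 18 such tests. At 19 to 60 nt the means were 56.4% ± 0.37 in sacy-1 and 57.2% ± 1.57 in N2 az02, a difference of -0.82 points within the spread (exact permutation p = 0.6). The differences of alternative 5′ splice sites were -0.25, 0.18 and 0.03 points in the 3 distance bins (exact permutation p = 0.4, 0.5 and 0.9).

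**Figure D1:**
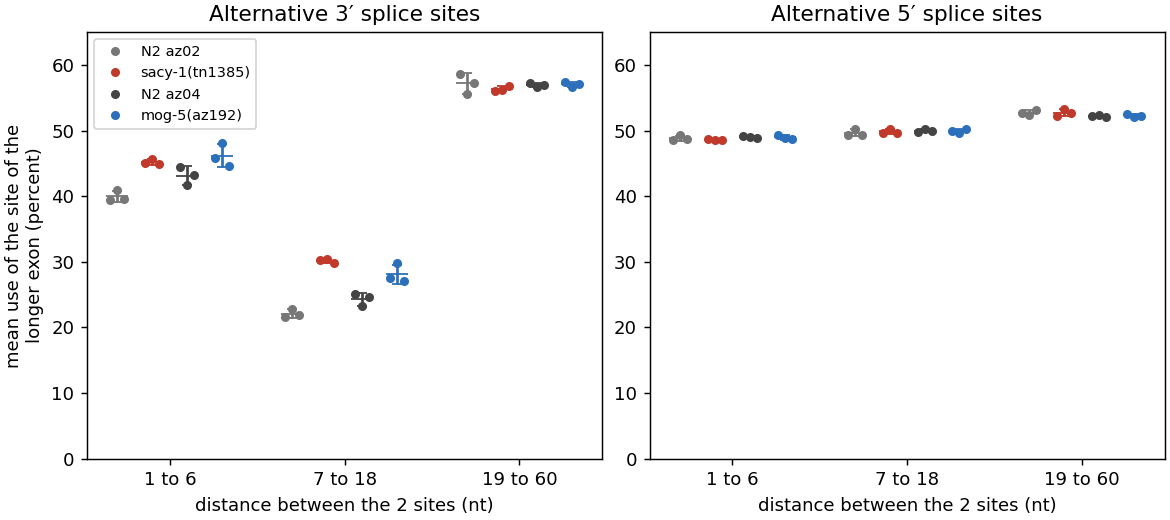
Mean use of the splice site that gives the longer exon (percent) per library, by distance between both sites (nt), for alternative 3′ sites (left) and alternative 5′ sites (right); points are libraries, bars the mean ± SD of 3 libraries. At 7 to 18 nt the sacy-1 libraries lie between 29.8% and 30.4% and the N2 az02 libraries between 21.7% and 22.8%, while alternative 5′ sites lie between 49.4% and 50.3% in all 12 libraries.

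**Figure D2:**
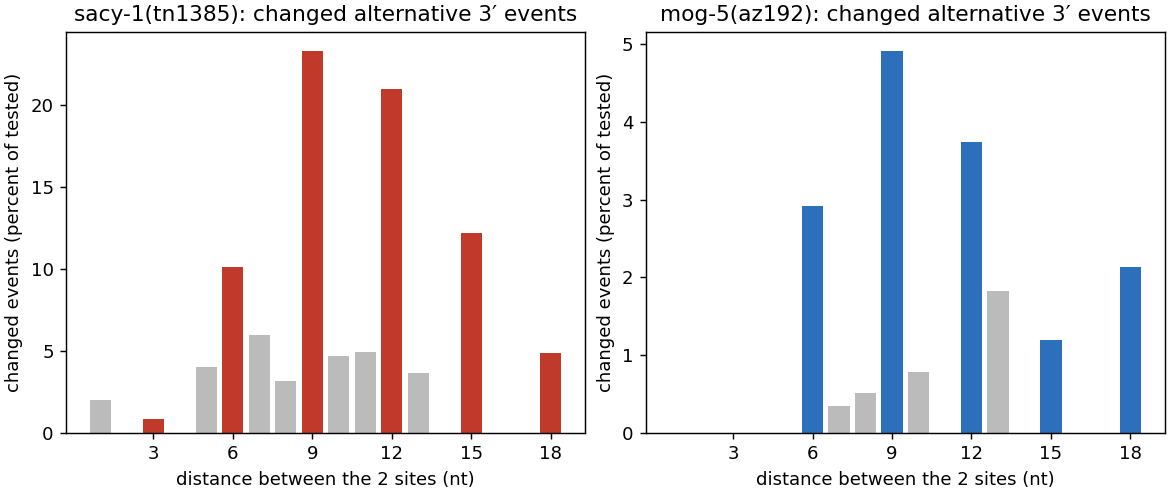
Share of tested alternative 3′ splice site events that changed (percent) by distance between both acceptors (1 to 18 nt), for sacy-1 (left) and mog-5 (right); coloured bars are multiples of 3 nt, and the vertical scales differ. The highest bars are at 9 nt, with 23.3% of 562 events in sacy-1 and 4.91% of 570 in mog-5.

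The largest upstream shift was on chromosome X, plus strand, in an event at 5286790 to 5287117 whose acceptors at 5286961 and 5286973 are 12 nt apart. Upstream use there was 85.7% ± 9.1 (SD, n = 3) in sacy-1 and 4.2% ± 4.5 in N2 az02 (limma adjusted p = 0.00183). On chromosome I, minus strand, at 7539111 to 7539445, the acceptors at 7539255 and 7539246 are 9 nt apart, and upstream use was 85.2% ± 3.5 against 10% ± 4.8 (adjusted p = 0.000514). On chromosome IV, minus strand, at 15999136 to 15999878, acceptors 15999282 and 15999276 are 6 nt apart, and upstream use was 82.6% ± 5.9 against 8.5% ± 2.9 (adjusted p = 0.000684). A pair 9 nt apart on chromosome III, plus strand, at 5118386 to 5118704 went from 9% ± 1.6 to 81.8% ± 1.9 (adjusted p = 8.08e-05). A pair 6 nt apart on chromosome V, minus strand, at 19121774 to 19122072 went from 9.5% ± 1.4 to 80.5% ± 1.8 (adjusted p = 8.08e-05).

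Chromosome II, minus strand, held a pair 9 nt apart at 12209620 to 12210895 with 82% ± 0.6 upstream use in sacy-1 and 10% ± 2.6 in N2 az02 (adjusted p = 0.000107). Chromosome X, minus strand, held a pair 6 nt apart at 10374533 to 10374856 with 75% ± 3.4 against 5.5% ± 2.7 (adjusted p = 0.000339). Chromosome I, plus strand, held a pair 12 nt apart at 5260285 to 5260585 with 81% ± 0.6 against 11.7% ± 5 (adjusted p = 0.000491). On chromosome II, plus strand, at 3298212 to 3298503, a pair 6 nt apart stood at 99.9% in the 3 sacy-1 libraries and at 21.7% ± 21.4 in N2 az02 (adjusted p = 0.0185). That last call was lost without az023, at a difference of 78.4 points, and without az024, az025 or az026, at 78.2 points each.

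A single event switched completely in the other direction. On chromosome II, minus strand, at 7497705 to 7497989, acceptors 7497812 and 7497769 are 43 nt apart, and upstream use was 0.1% in each of the 3 sacy-1 libraries and 99.9% in each of the other 9 libraries (limma adjusted p = 1.85e-07). The SD was 0 in both groups, so that p-value measured no spread between these libraries and rested on that of the other events. The remaining changed events of 19 to 60 nt, named after their values were seen, were few. Upstream use fell from 85.2% ± 7.7 to 55% ± 6.3 on chromosome III at 897066 to 897531 (adjusted p = 0.032) and from 63% ± 7.1 to 37.2% ± 5.3 on chromosome V at 7880979 to 7881340 (adjusted p = 0.0366). It rose from 6.1% ± 10.4 to 55.6% ± 9.6 on chromosome IV at 11505031 to 11505631 (adjusted p = 0.0209). That event shares its downstream acceptor at 11505509 with a changed pair 8 nt apart, which went from 30.4% ± 17.7 to 88.9% ± 4.8 in sacy-1. Less use of the shared acceptor would raise both percentages, so the 2 may not be separate changes.

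Alternative 3′ splice sites were changed more often in sacy-1 than the other event types together, with 9.29% of tested events called (odds ratio 16.6, Fisher's exact test, adjusted p = 1.14e-79 over 8 types). The catalogues were adjusted separately, so part of that ratio may reflect unlike unadjusted thresholds. At an unadjusted p below 0.05 lay 979 of 3370 alternative 3′ events and, in the same catalogue, 126 of 1699 alternative 5′ events. In the Ensembl catalogue 69 of 275 last exons, 76 of 566 skipped exons, 67 of 775 retained introns and 14 of 66 mutually exclusive exon events did so. Of 1699 alternative 5′ events 8 changed, of 275 alternative last exons 12 at 8 loci, of 66 mutually exclusive exon events 2, of 775 retained introns 2 and of 566 skipped exons 1. Each of the 12 last exon events held the acceptor pair of a called alternative 3′ event and changed by as many points, so they were not separate changes. No alternative first exon of 546 and no multiple skipped exon event of 154 was called by limma or on the arcsine square root scale, with 50 and 24 at an unadjusted p below 0.05. A skipped exon of 88 nt on chromosome X, minus strand, at 17386800 to 17386887 was included at 34.5% ± 2 in sacy-1 and 99.6% ± 0.5 in N2 az02 (limma adjusted p = 0.000107). Retention of a 53 nt intron on chromosome X at 10781037 to 10781089 rose from 54.4% ± 1.3 to 70.1% ± 1.8 (adjusted p = 0.0216), and retention of a 51 nt intron on chromosome III at 5505164 to 5505214 from 4.4% ± 0.5 to 20.1% ± 1.2 (adjusted p = 0.0049). The call at the 53 nt intron was lost without az021 (15.3 points), az022 (16.4), az023 (15.4), az024 (16), az025 (16.5) or az026 (14.7), and also against N2 az04 (11.5), against all 6 N2 libraries (13.6) and with a variance trend (15.7). That at the 51 nt intron was lost without az021 (15.4 points) or az025 (15.7) and against N2 az04 (14.4).

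Among alternative last exons, inclusion of the form the catalogue lists as included fell from 90% ± 2.6 to 18% ± 0.6 on chromosome II at 12209075 to 12211109 (limma adjusted p = 0.000167). It rose from 14.6% ± 1.9 to 76.4% ± 0.2 on chromosome IV at 6324715 to 6326391 (adjusted p = 0.000107). It fell from 62.8% ± 5.6 to 9.4% ± 3.7 on chromosome II at 10796527 to 10797025 (adjusted p = 0.0149), a call lost without az021 (-51.5 points), az023 (-52.2), az025 (-53.5) or az026 (-51.6), against N2 az04 (-31.6) and against all 6 N2 libraries (-42.5). Mutually exclusive exon events rose from 9% ± 2 to 32.5% ± 1.7 on chromosome I at 6125447 to 6125925 (adjusted p = 0.0138) and from 48.5% ± 1.3 to 70.7% ± 3.1 on chromosome II at 7605809 to 7606677 (adjusted p = 0.0232). The chromosome I call was lost without az021 (22.3 points), az023 (24), az025 (22.8) or az026 (23.2), and the chromosome II call without az021 (21.4), az022 (22.7), az023 (22.3), az024 (23) or az026 (23.1).

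The named alternative 5′ events were less even between libraries. The longer-exon form stood at 99.9% in the 3 sacy-1 libraries and at 16.7% ± 28.8 in N2 az02 on chromosome I at 1051919 to 1052230 (limma adjusted p = 0.0368). It was at 41% ± 2.5 against 92.5% ± 12.8 on chromosome X at 822546 to 822977 (adjusted p = 0.0144), and at 56.5% ± 12.3 against 99.9% on chromosome V at 9164398 to 9164749 (adjusted p = 0.0202). The chromosome I call was lost without az021 or az023 (74.9 points each), without az024, az025 or az026 (83.2 each) and against all 6 N2 libraries (61.7). The chromosome X call was lost without az021 or az023 (-47.8 points each), az024 (-51.6), az025 (-50.2) or az026 (-52.7) and against N2 az04 (-29.3), and the chromosome V call without az021, az022 or az023 (-43.4 each) or az024 (-45.1), against N2 az04 (-11.5) and against all 6 N2 libraries (-27.5).

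Over the whole library-intron catalogue, 321 of 5069 tested events changed in sacy-1, 313 to the included form and 8 away from it, at 305 loci. In each of the 321 events the 3 sacy-1 libraries lay on 1 side of the 3 N2 libraries. The test favours such events, and both events called between the wild-type sets showed it too, so it adds no support to the calls. Over all tested events, called or not, the pattern was seen in 29.1% for sacy-1 and in 17.7% between the wild-type sets, and 10% is expected by chance. Without a minimum difference the count was 506. Against N2 az04 it was 258, with 201 of the 321 among them, and against all 6 N2 libraries 311, with 253 of the 321. In the Ensembl catalogue 17 of 2382 events changed, at 13 loci. That count was 5 without az021, 11 without az022, 9 without az023, 7 without az025 and 7 without az026, and 69 against N2 az04.

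In mog-5(az192) larvae, the same kind of event changed in the same direction. Of 3433 alternative 3′ splice site events tested, 66 changed, and all 66 used the upstream acceptor more than N2 az04 did. By distance, 23 lay at 1 to 6 nt, 42 at 7 to 18 nt and 1 at 19 nt. Median upstream use over the 66 was 24.8% in N2 az04 and 61.2% in mog-5. Mean upstream use over the 1725 events of 7 to 18 nt was 28.1% ± 1.45 (SD, n = 3) in mog-5 and 24.3% ± 0.99 in N2 az04, a difference of 3.84 points.

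The direction again lay on 1 side of an even split (exact two-sided binomial test over events, p = 2.71e-20). Here too, an event with less upstream use in N2 az04 than the minimum difference could only be called upstream. An even split is not what the 2 wild-type sets gave. Up to 18 nt, 459 events leaned upstream and 49 downstream between them at an unadjusted p below 0.05. No event was called downstream by limma or on the arcsine square root scale, and 32 leaned downstream at an unadjusted p below 0.05. At 1 to 6 nt the means were 46.2% ± 1.82 in mog-5 and 43.2% ± 1.39 in N2 az04. Both short bins gave an exact two-sided permutation p = 0.1, the smallest possible, and at 19 to 60 nt the difference was 0.1 points (exact permutation p = 0.7). Alternative 3′ events were called at 1.92%, more often than the other types together (odds ratio 41.4, Fisher's exact test, adjusted p = 3.71e-20). Here too the catalogues were adjusted separately. At an unadjusted p below 0.05 lay 675 of 3433 alternative 3′ events, 121 of 1739 alternative 5′ events and, in the Ensembl catalogue, 46 of 283 last exons.

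The largest mog-5 shift was on chromosome X, minus strand, at 11124997 to 11125319, where acceptors 11125149 and 11125130 are 19 nt apart. Upstream use was 63.9% ± 12.7 in mog-5 and 0.1% in the 3 N2 az04 libraries (limma adjusted p = 0.0271), and the call was lost without az041, az042 or az043 (63.8 points each), az044 (58.2) or az045 (62.4) and in 1 fit of all 12 libraries (63.8). The mog-5 libraries stood at 75%, 66.67% and 50%, simple fractions that may rest on few reads, which could not be checked. The chromosome X pair at 5286961 and 5286973 went from 6.4% ± 2.9 to 59.2% ± 7.1 (adjusted p = 0.0148), a call lost without az041 (54.5 points), az042 (51.7), az043 (52.3) or az044 (51.7). The chromosome I pair at 7539255 and 7539246 went from 17.4% ± 2.7 to 63.1% ± 3.1 (adjusted p = 0.00472). The chromosome IV pair at 15999282 and 15999276 went from 6.6% ± 3.4 to 51.5% ± 2.7 (adjusted p = 0.00526). A pair 6 nt apart on chromosome I, plus strand, at 6125449 to 6125774 went from 22.8% ± 0.9 to 65.3% ± 0.5 (adjusted p = 0.000122). These last 3 calls held with each of the 6 libraries left out.

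The other named mog-5 events rose by 38.1 to 44.7 points. They lay on chromosome III at 11689572 to 11691340 (9 nt, 44.3% ± 4.9 to 89% ± 5.5, limma adjusted p = 0.0177), on chromosome I at 2765533 to 2765886 (18 nt, 22.8% ± 5.1 to 64.6% ± 3.7, adjusted p = 0.0158) and on chromosome X at 12975319 to 12975641 (9 nt, 10.1% ± 4.1 to 50.9% ± 7, adjusted p = 0.0271). Further pairs were on chromosome I at 7141858 to 7142205 (9 nt, 27.6% ± 2.6 to 66% ± 5.4, adjusted p = 0.016) and on chromosome IV at 11505031 to 11505631 (8 nt, 20.6% ± 3 to 58.7% ± 8.8, adjusted p = 0.0423). The chromosome III call was lost without az041 (41.9 points), az042 (46.2), az043 (46.1), az044 (44.8) or az045 (41.9), and that at 2765533 without az042 (39.7), az043 (41.1), az044 (40.3) or az045 (41.2). The chromosome X call was lost without az041 (40.2 points), az042 (39), az043 (43), az044 (38.1) or az046 (39.4) and against N2 az02 (34.8), and that at 7141858 without az041 (38.8), az042 (36.9), az043 (39.4) or az044 (37.4). The chromosome IV call was lost without az041 (36.5 points), az042 (38.4), az043 (39.5), az045 (34.8) or az046 (36.4) and against N2 az02 (28.3).

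A single alternative 5′ event changed in mog-5, on chromosome I at 5192717 to 5192986, from 4.2% ± 7.2 to 52.4% ± 9.6 (limma adjusted p = 0.0436). Its call was lost without az041 or az042 (46.1 points each), az043 (52.3), az044 (46.6), az045 (53.5) or az046 (44.4), on the arcsine square root scale and in 1 fit of all 12 libraries (48.2 each), against N2 az02 (19) and against all 6 N2 libraries (33.6). The mutually exclusive exon event on chromosome I at 6125447 to 6125925 went from 9.6% ± 0.3 to 24.7% ± 0.7 (adjusted p = 0.00372) and was the only call of 2498 events in the Ensembl catalogue, where 254 had an unadjusted p below 0.05 and the arcsine square root scale also called 1. That call was lost without az041 (15.2 points), az042 or az043 (14.9 each), az044 (15) or az046 (14.7). It was also lost under the pairwise rule, with a 20-point minimum and with a score sum of at least 500 per mille.

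The library-intron count for mog-5 was 67 of 5172 tested events, all 67 to the included form, at 65 loci. It rested on every library, being 32 without az041, 16 without az042, 15 without az043, 25 without az044, 35 without az045 and 42 without az046. It was 145 against N2 az02, with 50 of the 67 among them, and 132 against all 6 N2 libraries, with 60 of the 67. In each of the 67 events the 3 mog-5 libraries lay on 1 side of the 3 N2 libraries, which again follows largely from the test and adds no support. Over all tested events, called or not, the pattern was seen in 21.5% for mog-5 and in 17.7% between the wild-type sets, and 10% is expected by chance.

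The 2 wild-type sets were compared in the same way, since each mutant had its own. N2 az04 used the upstream acceptor of closely spaced pairs more than N2 az02 did. The mean at 7 to 18 nt was 24.3% ± 0.99 against 22.1% ± 0.62, a difference of 2.17 points, and at 1 to 6 nt 43.2% ± 1.39 against 39.99% ± 0.83, a difference of 3.18 points (exact permutation p = 0.1 for each, the smallest possible). These differences compare with 3.84 and 3.05 points between mog-5 and N2 az04. Of single events up to 18 nt none of 2973 was called by limma or on the arcsine square root scale, with 459 leaning upstream and 49 downstream at an unadjusted p below 0.05, and 1873 of the 2973 lay higher in N2 az04.

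Over the whole library-intron catalogue 2 of 5098 events were called between the wild-type sets, and both were named after their values were seen. Upstream use was 66.7% in each N2 az02 library and 29.1% ± 4.5 in N2 az04 at an alternative 3′ event on chromosome V at 9159822 to 9160176 (limma adjusted p = 0.0491). The longer-exon form was 99.9% in N2 az02 and 50.9% ± 5.9 in N2 az04 at an alternative 5′ event on chromosome III at 10982553 to 10985012 (adjusted p = 0.0491). Both events had an SD of 0 in N2 az02. Equal values such as 66.7% in each library may rest on few reads, which could not be checked. The count was 0 without az041, 8 without az022, 5 without az023 and 7 without az042. In the Ensembl catalogue 12 of 2405 events differed between the wild-type sets, against 17 in sacy-1 and 1 in mog-5, and that count was 3 without az021, 6 without az022, 0 without az042 and 3 without az043. The order of wild type and sacy-1 depended on the setting, with 42 between the wild-type sets, 31 in sacy-1 and 7 in mog-5 in 1 fit of all 12 libraries, and 41, 27 and 1 without a minimum difference. Of all tested Ensembl events 23.2% had non-overlapping wild-type sets, against 16.3% in sacy-1 and 13.8% in mog-5.

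Both mutants moved many of the same events upstream. Of the 5019 library-intron events tested in both, 313 moved to the included form in sacy-1 and 67 in mog-5, and 52 did so in both, where 4.18 would be shared by independent lists (Fisher's exact test, p = 4.95e-51). Of these lists 310 and 66 were alternative 3′ events, of which 3345 were tested in both, and both lists favoured similar distances. The 4.18 was taken over all 5019 events, alternative 5′ events included, so it is too low for these lists. The p-value therefore overstates the overlap, and no base matched for event type or distance was computed. The comparisons shared no libraries. Of the 310 alternative 3′ events that moved upstream in sacy-1, 302 were higher in mog-5 than in N2 az04, as were 2595 of all 3433 alternative 3′ events tested in mog-5, with a mean rise over the 310 of 34.2 ± 15.1 points in sacy-1 and 13.5 ± 10.1 in mog-5 (SD over events). Of the 66 that moved upstream in mog-5, 63 were higher in sacy-1 than in N2 az02, as were 2646 of all 3370 tested in sacy-1, with a mean rise over the 66 of 27.6 ± 10.3 points in mog-5 and 39.96 ± 22.1 in sacy-1. The mean rise in the mutant by which events were chosen is raised by that choice.

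Which mutant had the larger mean rise depended on the N2 set. At 7 to 18 nt it was 7.99 points in sacy-1 and 3.84 in mog-5 against their own sets, and 5.83 in sacy-1 and 6.01 in mog-5 with the sets exchanged. Mean upstream use was 30.1% ± 0.33 in sacy-1 and 28.1% ± 1.45 in mog-5 at 7 to 18 nt (SD, n = 3), and 45.2% ± 0.43 and 46.2% ± 1.82 at 1 to 6 nt, differences that were not tested.

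**Figure D3:**
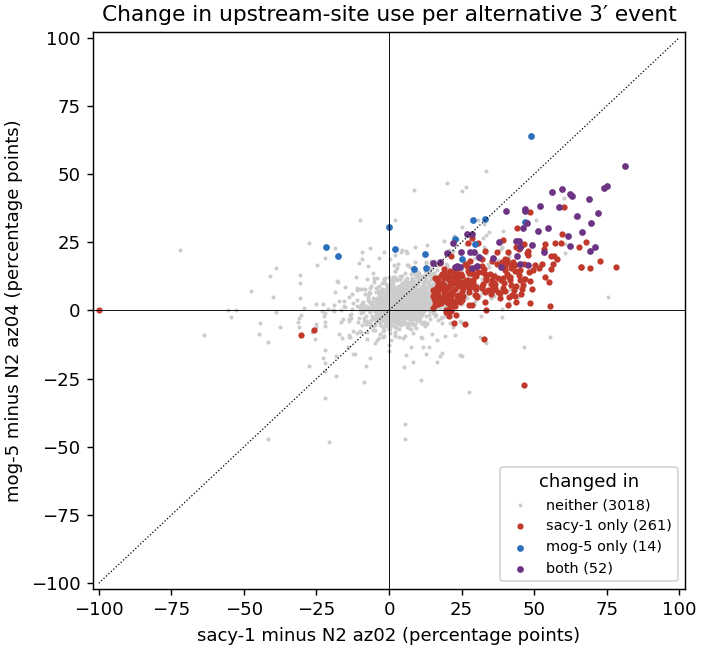
Change in upstream-acceptor use in sacy-1 (x axis, percentage points against N2 az02) and mog-5 (y axis, percentage points against N2 az04) for each of 3345 alternative 3′ splice site events, coloured by the mutant in which it was called; the dotted line marks equal change. The 52 events called in both lie in the upper right, and Pearson's r across events, which are not independent replicates, is 0.591.

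With 1 event taken per locus, the events with the largest rise in both mutants were the chromosome X pair at 5286961 and 5286973, the chromosome I pair at 7539255 and 7539246, the chromosome IV pair at 15999282 and 15999276, the chromosome III pair at 11691193 and 11691202 and the chromosome I pair at 6125647 and 6125653. At the last of these, upstream use was 83.9% ± 1.7 in sacy-1, 21.4% ± 5.8 in N2 az02, 65.3% ± 0.5 in mog-5 and 22.8% ± 0.9 in N2 az04. At the chromosome III pair it was 96.8% ± 2.8, 37.3% ± 4.8, 89% ± 5.5 and 44.3% ± 4.9 in the same order.

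**Figure D4:**
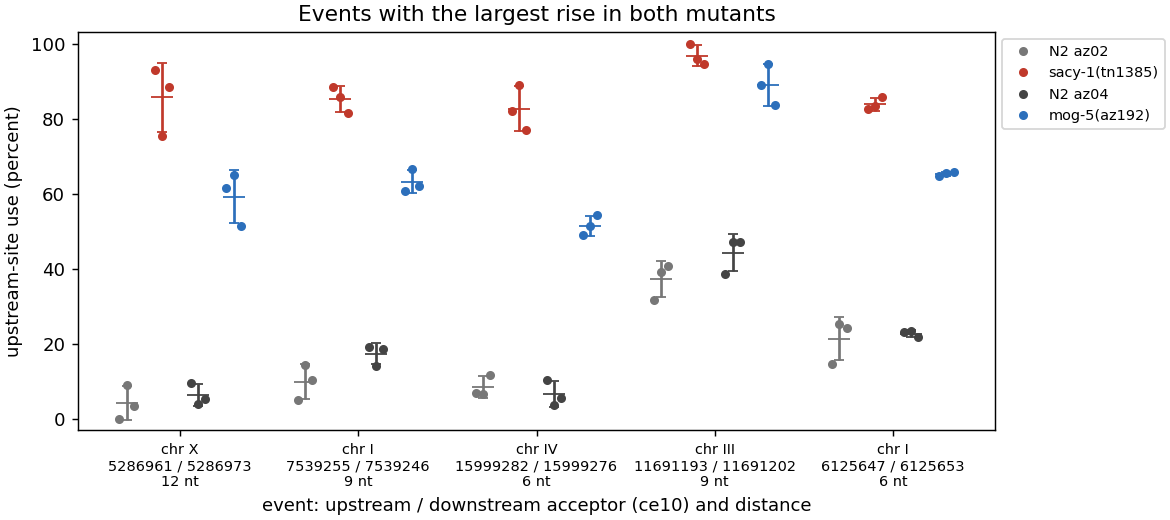
Upstream-acceptor use (percent) in the 4 groups at the 5 events with the largest rise in both mutants, labelled by chromosome, acceptor positions on ce10 and distance; points are libraries, bars the mean ± SD of 3 libraries. In each event the 3 libraries of each mutant lie above the 3 libraries of its N2 set.

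The difference between both mutant effects was called at 75 of 5019 events by the interaction term, with the larger rise in sacy-1 at 72, each an alternative 3′ event. At those 72 events mean upstream use was 57.6% in sacy-1, 34.95% in mog-5, 11.6% in N2 az02 and 20.8% in N2 az04, and choosing events by the interaction term widens the gaps between mutants and between wild-type sets. The other 3, named after their values were seen, were the chromosome II switch, an alternative 5′ event on chromosome I at 5240686 to 5241015 (73.7% ± 7.1 in sacy-1, 99.1% ± 1.4 in N2 az02 and 99.9% in mog-5 and N2 az04) and the alternative 5′ event on chromosome III at 10982553 to 10985012 (33.4% ± 28.8, 99.9%, 69% ± 13.3 and 50.9% ± 5.9 in sacy-1, N2 az02, mog-5 and N2 az04). A direct comparison of the sacy-1 with the mog-5 libraries, chosen after the data were seen, called 44 events, 40 of them higher in sacy-1, and 39 of the 75 were among the 44. The interaction count was 42 without az043, 42 without az044 and 115 without az045. Beside the complete switch on chromosome II, the library-intron events with the smallest adjusted p were both on chromosome X, plus strand. At 17600325 to 17600621 upstream use was 44.3% ± 2.6 in sacy-1, 0.5% ± 0.2 in N2 az02, 3.4% ± 0.4 in mog-5 and 0.3% ± 0.1 in N2 az04 (limma interaction adjusted p = 2.44e-06). At 3285241 to 3285416 it was 10.1% ± 0.4 in sacy-1 and 0.1% in each library of the other groups (interaction adjusted p = 2.74e-06), a difference of 10 points that is below the 15-point minimum.

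The overlap of 52 events rested on the mog-5 calls and was 25 without az041, 15 without az042, 12 without az043, 20 without az044, 27 without az045 and 31 without az046.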

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

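The test of the longer-exon form, the test of low events at a high mog-5 level and the question of the library sets were chosen after the results they bear on had been seen, as was the direct comparison of the mutants.

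The effects of sacy-1 and mog-5 differed, by the interaction term, at 75 events of the library-intron catalogue and 6 of the Ensembl catalogue. The difference, sacy-1 effect minus mog-5 effect in percentage points, was -99.8 at the chromosome II switch at 7497705 to 7497989 (limma adjusted p = 3.59e-15) and -66.1 at the skipped exon on chromosome X at 17386800 to 17386887 (adjusted p = 1.52e-08). At the switch each group had an SD of 0, so its p-value rested on the spread of the other events. It was 54.6 on chromosome III at 5118386 to 5118704, 47.7 on chromosome I at 5260285 to 5260585, 47.6 on chromosome V at 19121774 to 19122072 and 40.7 on chromosome X at 17600325 to 17600621. It was 37.4 on chromosome X at 10374533 to 10374856, 36.1 on chromosome II at 12209620 to 12210895, 29.4 on chromosome I at 7539111 to 7539445, 29.2 on chromosome IV at 15999136 to 15999878 and 19.9 on chromosome I at 6125449 to 6125774. Among alternative last exons it was -36.1 on chromosome II at 12209075 to 12211109 and 34.5 on chromosome IV at 6324715 to 6326391. Both hold the acceptor pair of a called alternative 3′ event, and the first repeats the 36.1 points at 12209620 to 12210895. Of 100 splits drawn within the 2 library sets, 8 gave as many library-intron events as the real 75, and the highest other gave 309. All 7 other splits that did so kept the sacy-1 and N2 az02 libraries apart, as 13 of the other splits did, and crossed labels between mog-5 and N2 az04. The mog-5 effect was then removed or added to that of sacy-1, and full exchange of those labels gave 481. Such splits carry the mutant effects themselves, so this count neither excluded chance nor spoke for it.

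The upstream direction of changes up to 18 nt was weighed against 2 technical explanations. If the catalogue had listed upstream acceptors because they were first seen in the mutants, events already used both ways in wild type would change in both directions. Of the called sacy-1 events at 10 to 90% upstream use in N2 az04, the set not used in that comparison, 240 of 240 moved upstream, which is 100% (exact binomial 95% interval 98.5 to 100). Some of them lay below the minimum difference in N2 az02 and could only be called upstream, such as the chromosome III pair at 5118386 to 5118704 (9%). Of the 240, 45 stood at 50 to 90% in N2 az04, where a fall had more room. A shift of all libraries of the mutant to the form with the longer exon was argued against by the other events, since 33.3% of the 12 called alternative 5′ and 19 to 60 nt alternative 3′ events moved to the included form (interval 9.92 to 65.1). The helicase variants stay as a hypothesis, with the genetic background of the strains and the authors' alignment untested and the difference between wild-type sets open.

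The wild-type sets differed in the same direction as the mutants, which bears on the size of both effects. If mog-5 RNA had entered the N2 az04 libraries, the shift would be the same share of the mog-5 difference at every level. Among events that rose by at least 30 points in sacy-1, chosen by their level in az022 and az023 and measured against az021, it was 40.9% (95% bootstrap interval 33.5 to 47.1) in 129 events at 10 to 50% and 23% (-106 to 69.3) in 20 events at up to 2%, which leaves it open. In 9 events at up to 2% in each N2 az02 library and at 20% or more in mog-5 it was 14.3% (3.89 to 24.5), too few events, chosen by the mog-5 level itself, to exclude it. A difference in culture or library making between both sets (2.17 points at 7 to 18 nt) cannot be told apart from the rest, because each set held 1 wild-type group and 1 mutant.

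With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the library-intron catalogue the real split gave 321 events for sacy-1 (1 of 10 splits gave as many, highest other 1), 67 for mog-5 (1 of 10, highest other 0) and 2 between the wild-type sets (2 of 10, highest other 2). In the Ensembl catalogue it gave 17 for sacy-1 (1 of 10, highest other 0), 1 for mog-5 (1 of 10, highest other 0) and 12 between the wild-type sets (1 of 10, highest other 1).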

How the results depend on the processing

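Over the counts, directions and means that answer the comparisons, 122 of 182 alternatives kept the direction and the side of the threshold, or left a count within 1.5 times and a mean within its spread, and 60 moved the value. Counts were scored on size alone and could not reverse. Of the directions and means, which could, 0 reversed. The arcsine scale outside the mutant counts, the pairwise rule, minimum differences and 1 fit of all 12 libraries for the wild-type sets, the variance trend, listing in 2 of 3 libraries, the score sum, loci, the direct comparison of mutants, and all alternatives for the mean use, the overlap and single named events were chosen after the data were seen. The share of called alternative 3′ events that moved upstream stayed between 91.5% and 100% in every alternative run for either mutant. Without a minimum difference the counts were 506 (sacy-1) and 139 (mog-5) in the library-intron catalogue, 27 for sacy-1 and 41 between wild-type sets in the Ensembl catalogue, and 90 for the overlap, since more events can pass. With the other N2 set, sacy-1 had 258 library-intron events, which held 201 of its 321 main calls, and mog-5 had 145, which held 50 of its 67. The Ensembl catalogue then gave 69 for sacy-1 and 39 for mog-5, and the overlap was 85. The mean difference at 7 to 18 nt was 5.83 points for sacy-1 and 6.01 for mog-5, and the cause was not tested. With all 6 N2 libraries, mog-5 had 132 library-intron and 7 Ensembl events, and the sacy-1 mean difference was 6.91 points. The sacy-1 count was then 311 in the library-intron catalogue, which held 253 of the 321 main calls. With all 12 libraries in 1 fit, the Ensembl counts were 31 for sacy-1, 7 for mog-5 and 42 between wild-type sets, and the overlap was 79; the cause was not tested. The single Ensembl mog-5 event was lost under the pairwise rule, which called 7 others, and the count was 0 with a 20-point minimum or a score sum of at least 500. The 12 Ensembl events between wild-type sets became 7 with a 20-point minimum. The 2 library-intron events between them became 4 on the arcsine scale or without a minimum difference, 29 under the pairwise rule, 1 with a variance trend and 0 with listing in 2 of 3 libraries. The interaction count of 75 became 44 in the direct comparison of mutants. Leaving out each library in turn gave 232 to 285 events for sacy-1, 15 to 42 for mog-5 and 0 to 8 between wild-type sets in the library-intron catalogue, and 5 to 14, 0 to 1 and 0 to 9 in the Ensembl catalogue. It gave upstream shares of 97.6% to 99.1% and 92.9% to 100%, mean differences of 7.76 to 8.34 and 3.01 to 4.37 points, 42 to 115 interaction events and 12 to 46 shared events, with fewer libraries per fit. The 33 named results kept their call in 297 of 396 alternatives, lost it with the same sign in 99 and reversed in 0. The pairwise rule, the other minimum differences and the score sum were left out of that tally. Alternatives on read minimums, count models, genes in place of events, reads per gene and exchange of catalogues, which hold different event types, were not run, because the values carry no reads or genes. Unknown depth limits how far an event at 0.1% or 99.9%, or at a simple fraction such as 66.7%, can be read.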

Other observations

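The tests of called shares by distance and the test of shared acceptor pairs were chosen after the result they measure had been seen, as were the summaries by level, intron length and locus.

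In sacy-1, 131 of 562 tested pairs at 9 nt changed (23.3%), 45 of 214 at 12 nt (21%), 79 of 780 at 6 nt (10.1%) and 10 of 82 at 15 nt (12.2%), but 2 of 231 at 3 nt (0.866%). In mog-5, 28 of 570 changed at 9 nt (4.91%), 8 of 214 at 12 nt (3.74%), 23 of 788 at 6 nt (2.92%) and 1 of 83 at 15 nt (1.2%). At 3 nt 0 of 235 changed in mog-5 by limma or on the arcsine square root scale, with 25 at an unadjusted p below 0.05. Of pairs at 10 to 50% upstream use in N2 az04, 25.1% changed in sacy-1, against 14.8% of those at 50 to 90%, 9.31% of those at 2 to 10% and 2.56% of those at up to 2%. Over 90% the share was 0.192%, where the 15-point minimum leaves little room to rise. Of pairs whose longer intron was under 70 nt 11.6% changed in sacy-1, and of the others 9.19% (Fisher's exact test, p = 0.0306, adjusted p = 0.0612). In mog-5 the shares were 2.36% and 1.96% (adjusted p = 0.455).

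Pairs at 6, 9, 12 or 15 nt changed more often than pairs at the distances beside them, a set chosen after the shares were seen that leaves out 3 nt, where in-frame pairs seldom changed. Of 1638 such pairs 16.2% changed in sacy-1, and of 894 pairs at the 8 neighbouring distances 4.36%, a ratio of 3.71 (95% bootstrap interval 2.8 to 5.39), which argues against a smooth dependence on distance. With 3 and 18 nt included, 269 of 1910 pairs at multiples of 3 changed (14.1%) and 40 of 1053 at other distances up to 18 nt (3.8%). A smaller spread between libraries was argued against by the mean rise, 9.58 points against 4.36 points, a ratio of 2.2 (1.88 to 2.59), and by a mean SD that was larger at these pairs (4.52 against 3.56 points). A candidate explanation is loss of frame-shifted RNAs by nonsense-mediated decay, the pathway that degrades mRNAs with early stop codons, which was not tested here and does not by itself account for the low share at 3 nt (0.866%).

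Most Ensembl-catalogue events called in sacy-1 held the acceptor pair of a called alternative 3′ event. Of the 17 called events 14 did so (82.4%), 12 of them the alternative last exons, against 9 of 2365 events that were not called (0.381%). Several of these events list the same locus again, and by locus 10 of 13 called loci held such a pair, against 7 of 1578 others. The differences of the 12 last exon events equal those of their pairs in size, so they were the same changes listed under another type. The mutually exclusive exon events moved less than their pairs, by 23.5 against 62.4 points on chromosome I at 6125447 to 6125925 and by 22.2 against 47.9 on chromosome II at 7605809 to 7606677. The other 3 were the retained introns on chromosome X at 10781037 to 10781089 and chromosome III at 5505164 to 5505214 and the skipped exon on chromosome X at 17386800 to 17386887. That skipped exon and the chromosome II switch at 7497705 to 7497989 were private to the 3 sacy-1 libraries, at 34.5% and 0.1% against at least 97.6% in each of the other 9 libraries.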
